A study of Mus musculus with 14 samples.

How the data were processed

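Whole-exome sequencing was carried out on DNA from 12 mouse mammary tumours, 3 in each of 4 groups, and on 2 wild-type tail samples, which were not analysed here. Per the labels' protocols, exons were captured with the SureSelectXT mouse kit and sequenced as 150 bp read pairs on either of a pair of Illumina NovaSeq models, with a stated depth above 50x and 6 Gb per sample. The labels do not say which tumour was run on which instrument. Per the submitters' processing notes, BWA 2.2.1, SAMtools 1.19.2 and GATK were used and GRCm39 was the genome build; the variant caller's settings, the filters, and any use of the tails as matched normals are not given in the sources used here. The counts may therefore hold inherited strain differences from the reference and false calls as well as somatic changes.

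The values are whole-number counts of variants per transcript, in tables deposited by the authors and written by snpEff, per the file headers. Each table splits the variants of a transcript by predicted impact (HIGH, such as a stop gained or a frameshift; MODERATE, such as a missense change; LOW, such as a synonymous change; MODIFIER, mostly intronic and flanking) and by type of effect. A transcript is listed only if it has a variant, so an unlisted transcript was taken as 0. The tables hold no read depth, position, base change or allele fraction, so the depth behind a count is unknown, no mutational spectrum was computed, and no genomic coordinates are given. The gene names follow an older annotation: 97.3% of the 21312 protein-coding gene symbols match a GRCm38.p6 gene table, which was used only for names and for which genes neighbour each other. Rows with a blank biotype, between 8962 and 11049 per tumour, were left out of the protein-coding counts.

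The count of a gene was, for each impact class, the maximum over its protein-coding transcripts, so that a variant was not counted once per transcript. A variant whose impact differs between transcripts can count in several classes, and variants in different transcripts can be missed. A variant in overlapping genes still counts in each of them. Coding variants are the sum of HIGH, MODERATE and LOW, and protein-altering variants the sum of HIGH and MODERATE; a tumour's burden is the sum over protein-coding genes. The non-shared burden subtracts, per gene, the lowest count among the 12 tumours. As that subtracts the same number, 7601, from each tumour, it leaves every difference between groups as it was and changes only the percentage.

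Groups were compared by two-sided exact permutation tests. With 3 tumours against 3 there are 20 assignments and the smallest possible p is 0.1, so no such test can pass 0.05. Labels were permuted within each experiment for the combined tests (400 assignments, smallest p 0.005), and over 924 assignments for the gel tumours against the host tumours. The protein-altering counts per gene, for genes with a sum of at least 3 over the 6 tumours, were tested with edgeR 4.0.16 (quasi-likelihood test, equal library sizes, Benjamini-Hochberg adjustment, threshold 0.05), with DESeq2 1.42.0 as an alternative. The SE printed with an edgeR fold change is not given by edgeR. It was computed as the absolute log2 fold change over the square root of the F statistic, and is only approximate. Genes with a protein-altering variant in 3 of 3 tumours of one group and 0 of 3 of the other were counted as all-or-none genes. Burdens of 12 gene lists and 13 multigene families were compared by the same exact test, adjusted over these 25. Labels say only that each tumour is a separate sample, so the p-values measure the spread between these tumours.

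The groups, tests, lists and most alternatives were set before the data were examined. The genes named are Trp53, Gpx4 and Lyz2, up to 10 genes per direction past the edgeR threshold, the 10 all-or-none genes per direction with the largest difference in mean count, and the 2 members of each list with the largest difference; members of multigene families were described only as families. A selection of these is printed. Some items are not reported here. The alternatives changed how transcripts were collapsed, the biotypes, the count filter, the impact classes, the scaling, the tool and the tumours included. Tumours A9 and B5 were also left out together, a choice made after seeing the data.

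The tests were tried on simulated data. In the gel comparison 200 changed genes had a mean count of at least 5, and 3751 simulated genes passed the filter for testing. Of the changed genes, edgeR recovered 2% of 2-fold, 46% of 4-fold, 82% of 8-fold and 94% of 16-fold changes. In the host comparison, with 4684 simulated genes tested, it recovered 0%, 4%, 30% and 60% of the same fold changes. These simulations gave every gene the same dispersion, 0.00359 for the gel and 0.0884 for the host comparison. Some real genes spread more within a group, such as Tnxb with 62, 41 and 23 in stiff tumours, so real recovery may be lower. For changed genes drawn at the counts seen in most genes it recovered at most 4% at any of these sizes in either comparison. The 200 planted all-or-none genes were set to meet the criterion without noise, so finding all of them only checked the counting. The other genes were drawn with Poisson noise. Of the genes with the same mean in both groups, 117 also met the criterion in the gel comparison and 101 in the host comparison, out of 21312 genes in all. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.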

Results

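Variant counts per gene were compared between p53null mammary tumours that grew in different surroundings. In the gel experiment, p53null mammary fragments of Balb/c mice were implanted into fat pads holding a collagen 1 and basement membrane gel, left soft or stiffened by crosslinking the collagen with 500 mM L-ribose. In the host experiment, fragments were implanted into LysM-Cre mice, in which Cre is active in myeloid cells, either wild-type (WT) or knockout (KO) for Gpx4, a peroxidase that removes lipid peroxides. The study asked how tissue tension and oxidative stress relate to DNA damage. Tumours A1, A2 and A3 were soft, A7, A8 and A9 stiff, B1, B2 and B3 from WT hosts, and B4, B5 and B6 from KO hosts.

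The tumours held between 14434 and 27337 coding variants. The lowest counts of each gene among the 12 tumours summed to 7601, only a rough guide to the variants that all could share, since positions are not listed. At least 1 protein-altering variant was found in 11835 of 21312 protein-coding genes. Of these genes, 1593 had one in all 12 tumours and 3855 in a single tumour. The gene with the most coding variants was Arhgap30 (ENSMUSG00000048865), with 68 to 136 protein-altering variants per tumour. Tnxb, which encodes the matrix protein tenascin-X, had 20 to 62; the top genes by coding count were looked up after the data were seen.

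Trp53 (ENSMUSG00000059552) had 1 protein-altering variant in A2, 2 in B1 and 1 in B4, and 0 in the other tumours. Gpx4 (ENSMUSG00000075706) and Lyz2 (ENSMUSG00000069516), the locus that drives LysM-Cre, had 0 coding variants in all 12 tumours. A null allele made by a large deletion is not listed in counts of this kind, and the Gpx4 knockout is in host cells, so these counts do not check the labels.

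In the gel comparison, which addresses tissue stiffness, stiff tumours carried fewer coding variants than soft tumours on average, and the groups overlapped. The mean was 16281 ± 805 (SD, n = 3) in stiff and 17966 ± 1419 (SD, n = 3) in soft tumours, a change of -9.38% (exact permutation p = 0.2). Protein-altering variants averaged 9690 ± 660 against 10751 ± 884 (exact permutation p = 0.2), and HIGH-impact variants 2601 ± 429 against 2949 ± 266 (exact permutation p = 0.5), a difference of -348 that was -103 without A9 and -207 without A2. Without A2 the difference in coding variants was -938, against -1685 with it, and that in protein-altering variants was -600 against -1061. Stop-gained variants averaged 464 ± 19.1 in stiff and 510 ± 24.2 in soft tumours, with no overlap (exact permutation p = 0.1, the smallest possible, adjusted 0.28). Splice donor or acceptor, splice region, 3' UTR and intron variants reached the same exact permutation p. Per 100 missense variants, stop-gained variants averaged 6.90 in stiff and 6.94 in soft tumours. MODIFIER variants were lower by a larger share than coding variants, -13.9% (exact permutation p = 0.1). Per 100 MODIFIER variants the direction turned: stiff tumours had 4.56 ± 0.0548 coding variants and soft tumours 4.33 ± 0.0315, with no overlap (exact permutation p = 0.1).

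**Figure D1:**
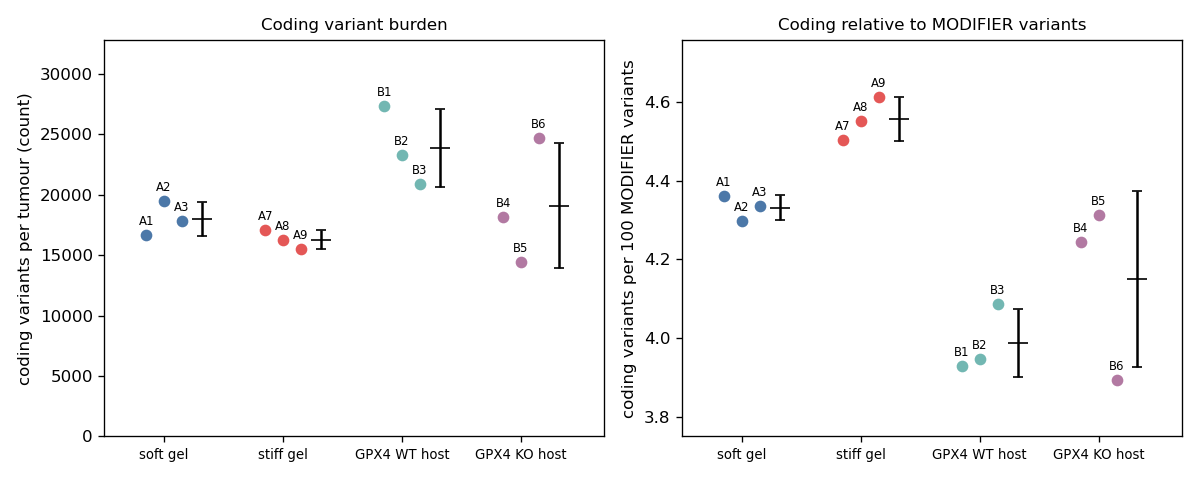
Coding variants per tumour (left, count) and coding variants per 100 MODIFIER variants (right, axis not starting at 0) in the 4 groups; points are tumours and black marks are the mean and SD of 3 tumours. Stiff tumours averaged 16281 coding variants against 17966 in soft tumours, but 4.56 against 4.33 per 100 MODIFIER variants.

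No single gene passed the test between stiff and soft tumours. edgeR tested 4312 genes and called 0 at an adjusted p under 0.05, with 106 at an unadjusted p under 0.05, 32 higher and 74 lower in stiff tumours (50 and 62 when scaled to each tumour's total protein-altering count); DESeq2 also called 0, with 7 at an unadjusted p under 0.05. There were 90 all-or-none genes, 31 with variants only in stiff tumours and 59 only in soft tumours, and 11 of the 90 belonged to multigene families. Counts simulated with the same mean in both groups gave 117 such genes. The other splits of the 6 tumours gave 57 to 92, all below 117, so the simulation is a poor guide here. As another split gave more than the real one, chance is not excluded, and the genes named here may be chance. Among those of soft tumours, Map1b, a microtubule-associated protein, had 5, 6 and 4 protein-altering variants in A1, A2 and A3. Ppp1r10, a regulatory subunit of protein phosphatase 1, had 3, 3 and 7, and Otogl, an otogelin-like protein, had 3, 2 and 3. Among those of stiff tumours, Fam72a had 2, 6 and 3 in A7, A8 and A9, and Celsr3, an adhesion receptor of the cadherin family, had 2, 3 and 1. Tut4, an RNA uridylyltransferase, had 3, 2 and 1, and Col12a1, a collagen chain, had 2, 1 and 1. Requiring 2 of 2 tumours is easier to meet, so leaving out any stiff tumour turned the side with more genes (112 in stiff and 102 in soft tumours without A7, 107 and 96 without A8, 102 and 78 without A9). Leaving out any soft tumour moved it the other way (46 and 229 without A1, 62 and 148 without A2, 56 and 187 without A3).

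Of the 12 lists fixed beforehand, 8 had a lower and 3 a higher mean protein-altering count in stiff tumours, 0 were without overlap, and the smallest adjusted p was 0.769 (exact permutation tests). Mammary tumour drivers (with median transcripts or with LOW-impact variants included), nucleotide excision repair genes and very long genes (with median transcripts) reached the smallest possible exact permutation p of 0.1, each lower in stiff tumours. No member of any list passed edgeR's test over all genes, and 0 passed when adjusted over the list alone. Base excision repair genes averaged 6.67 ± 2.08 variants in stiff and 6.67 ± 2.31 in soft tumours. Polb, the gap-filling polymerase of that pathway, averaged 1 against 2 ± 1.73, a difference that was 0 without A2. In mismatch repair, Pole, the leading-strand polymerase, averaged 5.33 ± 2.31 against 3.67 ± 1.15, a difference of 1.67 that was 0.333 without A7. Homologous recombination and Fanconi genes averaged 12 ± 2.65 against 17 ± 7.55, and Fancl had 6 and 5 variants in A1 and A2 and 0 in the other gel tumours. Ferroptosis and antioxidant genes averaged 12.3 ± 3.79 against 10 ± 4.58, with Tfrc, the transferrin receptor, at 2.67 ± 0.577 against 1 ± 1. Collagen and matrix genes averaged 80 ± 22.9 against 103 ± 24.4, and Hspg2, which encodes perlecan, 1.67 ± 0.577 against 8.67 ± 7.02. The Hspg2 difference of -7 was -3.33 without A2. Mammary tumour drivers averaged 63.7 ± 7.02 against 73.7 ± 2.52, with Notch3 at 0.333 ± 0.577 against 3.33 ± 0.577 (edgeR log2 fold change -2.92, SE 0.74, adjusted p = 1). Macrophage and myeloid genes averaged 12.7 ± 6.66 against 17.7 ± 2.52, and Cd163, a scavenger receptor of macrophages, had 1 variant in each soft tumour and 0 in each stiff tumour. Mismatch repair genes averaged 28.7 ± 5.03 against 30.7 ± 7.23, end joining genes 13.3 ± 2.08 against 12.3 ± 1.15, and nucleotide excision repair and translesion genes 17.7 ± 3.06 against 20.7 ± 2.52. Damage checkpoint genes averaged 8.33 ± 0.577 against 9 ± 1.73, and adhesion and mechanosignalling genes 45.7 ± 5.13 against 44.3 ± 6.43. Very long genes averaged 176 ± 6.51 against 186 ± 13.5; among them, Lrp2 averaged 6 ± 1.73 against 14.3 ± 2.52, while Ttn, which encodes titin, averaged 10.3 ± 3.79 against 5.67 ± 0.577. Of the families, vomeronasal receptors, zinc finger genes, killer cell lectin-like receptors and Skint genes were lower in every stiff tumour than in every soft tumour (exact permutation p = 0.1 each, adjusted 0.625). Vomeronasal receptors averaged 95 ± 38.7 against 137 ± 8.5. Within that family, A9 had 0 coding calls in Vmn2r37 and Vmn1r3, where the tumours other than A9 and B5 had at least 5 and 9. With LOW-impact variants included, the lectin-like receptors had an exact permutation p of 0.2; short reads of such near-identical copies are uncertain.

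In the host comparison, which addresses lipid peroxidation in myeloid cells, tumours of KO hosts carried fewer coding variants on average than those of WT hosts, and again the groups overlapped. The mean was 19090 ± 5182 (SD, n = 3) in KO and 23847 ± 3246 (SD, n = 3) in WT hosts, a change of -19.9% (exact permutation p = 0.3). The KO tumours were widely spread, with 18163 in B4, 14434 in B5 and 24672 in B6. Protein-altering variants averaged 11333 ± 3279 against 14392 ± 1997, and HIGH-impact variants 3018 ± 988 against 3989 ± 649 (exact permutation p = 0.3 for both). MODIFIER variants differed by -22.3% (exact permutation p = 0.3), and the KO tumours were again widely spread, with 428066 in B4, 334678 in B5 and 633594 in B6. Per 100 MODIFIER variants the direction turned here too, with 4.15 ± 0.224 coding variants in KO and 3.99 ± 0.086 in WT hosts (exact permutation p = 0.4). That difference of 0.163 was 0.0813 without B5 and 0.291, with no overlap, without B6. The difference in coding variants was -4757 over all tumours, -2430 without B5, -3012 without B1 and -7549 without B6. The difference in protein-altering variants was -3059 over all tumours, -1552 without B5, -1983 without B1 and -4805 without B6. The difference in HIGH-impact variants was -971 over all tumours, -490 without B5, -641 without B1 and -1477 without B6.

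No gene passed the test between KO and WT hosts. edgeR tested 5309 genes and called 0 at an adjusted p under 0.05, with 199 at an unadjusted p under 0.05, 26 higher and 173 lower in KO hosts (69 and 127 when scaled to each tumour's total); DESeq2 also called 0, with 28 at an unadjusted p under 0.05. There were 127 all-or-none genes, 23 with variants only in KO and 104 only in WT hosts, and 19 of the 127 belonged to multigene families. Counts simulated with the same mean in both groups gave 101 such genes, and another split of the 6 tumours gave 167, so the genes named here may be chance. Among those of WT hosts, Tas2r106, a bitter taste receptor with close relatives in the genome, had 10, 14 and 5 protein-altering variants in B1, B2 and B3. Gsg1 had 6, 4 and 4, Htr2b, a serotonin receptor, had 4, 3 and 4, and Dock2, a regulator of leukocyte migration, had 1, 3 and 3. Among those of KO hosts, Tmem37 had 6, 2 and 2 in B4, B5 and B6. Prdx1, a peroxide-removing peroxiredoxin, had 4, 1 and 4, and Cnot3, a subunit of the main mRNA deadenylase complex, had 2, 2 and 2. Ccne2, which encodes cyclin E2, had 1, 2 and 3. Leaving out a KO tumour gave 105 genes in KO and 182 in WT hosts without B4, 142 and 144 without B5, and 66 and 255 without B6. Leaving out a WT tumour left more of them in WT hosts each time (44 and 217 without B1, 37 and 313 without B3).

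Most gene lists had lower counts in KO hosts, in parallel with the total. Of the 12 lists, 10 had a lower and 1 a higher mean, and the smallest adjusted p was 0.682 (exact permutation tests). No member of any list passed edgeR's test over all genes, and 0 passed when adjusted over the list alone. Mammary tumour drivers were the one list without overlap, at 75.7 ± 16.9 in KO and 98.7 ± 11.6 in WT hosts (exact permutation p = 0.1, adjusted 0.682). The groups overlapped with median transcripts or with LOW-impact variants included (exact permutation p = 0.2 for both). Of its members, 14 had a higher and 14 a lower mean in KO hosts, and Notch4 (-7) and Arid1a (-13) carried most of the -23 for the list. Arid1a, a chromatin remodelling subunit, averaged 8.67 ± 2.08 against 21.7 ± 7.64 (edgeR log2 fold change -1.31, SE 0.35, adjusted p = 1). Ferroptosis and antioxidant genes were the list with the higher mean, 24.7 ± 9.02 against 17.7 ± 5.51 (exact permutation p = 0.3). Within it, Prdx1 averaged 3 ± 1.73 against 0, while Gsr, glutathione reductase, averaged 0.333 ± 0.577 against 4 ± 1. Of that list's members, 10 had a higher and 7 a lower mean. Base excision repair genes averaged 9.67 ± 7.23 against 9.67 ± 2.52. Mismatch repair genes averaged 25.3 ± 3.51 against 31.3 ± 4.73, with Msh6 at 9 in each KO tumour and 12.7 ± 2.52 in WT hosts. Homologous recombination and Fanconi genes averaged 14 ± 4.36 against 15.7 ± 7.57, with Fanca at 4.33 ± 1.53 against 1.67 ± 1.53. Collagen and matrix genes averaged 96 ± 48.5 against 134 ± 11.4. Adhesion and mechanosignalling genes averaged 54.3 ± 16 against 67.7 ± 10.7, and the adaptor Bcar1 1 ± 1.73 against 4.67 ± 3.79. The Bcar1 difference of -3.67 was -1.5 without B1. End joining genes averaged 11.3 ± 2.08 against 13 ± 1, nucleotide excision repair and translesion genes 18.7 ± 7.23 against 23 in each WT tumour, damage checkpoint genes 10.3 ± 5.51 against 11.7 ± 1.15, and very long genes 195 ± 40.5 against 221 ± 32.9. Macrophage and myeloid genes averaged 17.3 ± 6.43 against 20.7 ± 8.02. Of the families, keratin-associated proteins and defensins were lower in every KO tumour than in every WT tumour (exact permutation p = 0.1 each, adjusted 0.682). With LOW-impact variants included, keratin-associated proteins had an exact permutation p of 0.2.

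Across both experiments, the 2 differences in coding variants summed to -6442 (exact permutation p = 0.11, labels permuted within each experiment). That sum was -9234 without B6 (exact permutation p = 0.015) and -4115 without B5 (exact permutation p = 0.265). Per 100 MODIFIER variants the sum was 0.388 and of the opposite sign (exact permutation p = 0.035). The difference between the experiments' effects was 3072 (exact permutation p = 0.47), and 744 without B5, 1327 without B1 and 5864 without B6. Gel tumours held fewer coding variants than host tumours, 17123 ± 1385 (SD, n = 6) against 21468 ± 4663 (SD, n = 6), with an exact permutation p of 0.0584. Without B5 that difference was -5752 (exact permutation p = 0.00433) and without B4 it was -5006 (exact permutation p = 0.0433). Leaving out any of the other 10 tumours gave an exact permutation p between 0.0563 (without A2) and 0.113 (without B1). Per 100 MODIFIER variants the direction turned, with 0.376 more coding variants in gel tumours (exact permutation p = 0.00433). Within each of the 4 groups, tumours with fewer MODIFIER variants also had more coding variants per 100 of them, so such a turn need not follow the experiment or group. Gels, hosts and possibly sequencing runs differ between the experiments and cannot be told apart.

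The kinds of coding change were alike in most tumours. Stop-gained variants numbered 6.27 to 7.16 per 100 missense variants in the 12 tumours, and synonymous variants 76.4 to 82.6. Frameshift variants numbered 27.7 to 30.8 per 100 missense variants in 10 tumours, 19.9 in stiff tumour A9 and 23.1 in KO-host tumour B5. These 2 tumours also held the fewest coding variants of all 12, and both belong to the groups with the lower means.

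**Figure D2:**
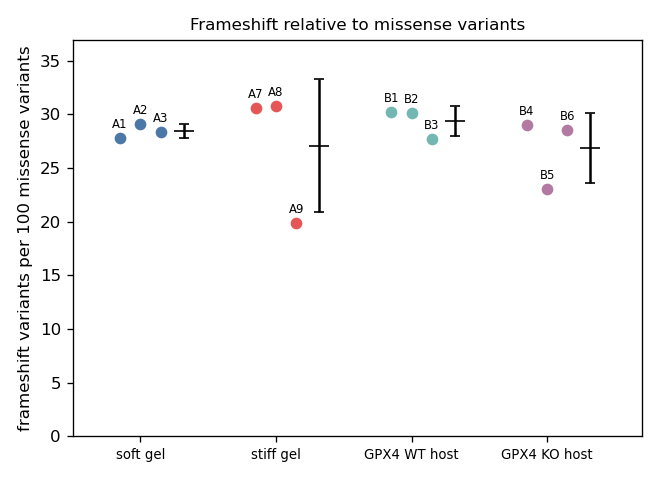
Frameshift variants per 100 missense variants in each tumour of the 4 groups; points are tumours and black marks are the mean and SD of 3 tumours. A9 at 19.9 and B5 at 23.1 lie below the other 10 tumours, which span 27.7 to 30.8.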

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

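Leaving out A9 and B5, and leaving out single tumours in the 3 combined results, were chosen after seeing the data. No alternative gave a gene past the edgeR or DESeq2 threshold. The absolute burdens kept their direction under all alternatives that count variants. Relative to MODIFIER variants they reversed: 0.225 (stiff minus soft), 0.163 (KO minus WT), 0.388 (both experiments) and 0.376 (gel minus host); MODIFIER counts were lower by a larger share than coding counts. Gel minus host passed 0.05 without the top 1% of genes (-3885) and without A9 and B5 (-5425). Without single tumours, coding burden ranged from -2351 to -938 (stiff minus soft), -7549 to -2430 (KO minus WT), -9234 to -4115 (both; exact permutation p = 0.015 without B6 and 0.075 to 0.27 without any other tumour), -5752 to -3171 (gel minus host) and 744 to 5864 (difference between the experiments); protein-altering burden from -1482 to -600 and -4805 to -1552, and HIGH-impact burden from -505 to -103 and -1477 to -490. All-or-none genes numbered 33 and 76 with HIGH-impact variants only, 167 and 265 as genes without overlap (at most 156 and 389 in other splits; ties keep the chance share under 10% per gene), 180 and 286 without A9 and B5, and 180 to 275 and 261 to 350 without single tumours (gel and host comparison), fewer tumours making the criterion easier. Of 25 lists and families, 4 and 3 were without overlap; median transcripts gave 7 and 2, LOW included 4 and 2, and leaving out single tumours 4 to 8 and 3 to 15 (15 without B6). In all, 5 list differences, none past a test, changed sign: adhesion (-2.67, median transcripts), immunoglobulin segments (-11 and -77, all biotypes), damage checkpoint (1.67) and keratin-associated proteins (0.333) with LOW included; the cause was not tested. Read depth is not in the tables, so its limit on these counts is unknown.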

Other observations

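Counting splits of 3 tumours against 3 and relating coding to MODIFIER variants were planned. What these would show, and every other test in this part, was set down only after the results were seen. Between the 2 experiments, 7 genes had a protein-altering variant in all 6 host tumours and in 0 of 6 gel tumours, and 0 genes the reverse. They were Amdhd1, Cmpk2, Ercc6l2, Ring1, Ankle1, Atp10b and Exoc5, named after their values were seen. Ercc6l2, a DNA repair helicase, averaged 5 variants in host tumours, and Amdhd1 averaged 5.67. Of 100 splits of the 12 tumours drawn at random, the real one included, 1 gave as many such genes (7, against at most 6 in the others). That margin is small and the test was set after the values were seen, so chance is not excluded. Host tumours also held more coding variants on average (21468 against 17123), which by itself favours genes found only in them. Which difference between the experiments the 7 genes follow was not tested.

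For 3 tumours against 3 there are 10 splits, too few for a share under 0.05. The stiff and soft tumours gave 90 all-or-none genes, against at most 92 in another split, and 2 of the 10 splits gave as many. The KO and WT host tumours gave 127, against at most 167, and again 2 of 10 gave as many. edgeR called 0 genes in all 10 splits of either comparison; at an unadjusted p under 0.05 the real splits gave 106 and 199 genes, against at most 104 and 294 in the others.

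The lower coding burden of stiff tumours and of KO-host tumours came with lower MODIFIER counts. A drop of the same share in coding and MODIFIER calls, whether from calling or from mutation, would leave the number of coding calls per 100 MODIFIER calls as it was. That number was higher by 0.225 in stiff tumours, with no overlap (exact permutation p = 0.1, the smallest possible). Too few tumours were compared to decide against such a drop there. Within each group, too, the number was higher in tumours with fewer MODIFIER variants. In KO-host tumours it was higher by 0.163 with overlapping groups (0.0813 without B5, and 0.291 with no overlap without B6), so a drop of the same share stays open there too. Fewer reads outside the captured exons might lower MODIFIER calls more than coding calls; this was not tested, as the tables hold no depth.

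Tumours A9 and B5, of different groups and experiments, may share a library or sequencing difference. In 17 genes, each of the 10 other tumours had at least 5 coding calls and both A9 and B5 at most 1, among them Pop4 (15 to 19 in the others), Adam4 (24 to 35) and Csprs (15 to 19); the highest count for any of the other 65 pairs was 1. Many of the 17 belong to multigene families, such as vomeronasal receptors and major urinary proteins, or are predicted genes, where short reads of copies are uncertain. Fewer calls in total, spread over all genes, are argued against, as A9 had at most 1 coding call in 20 and B5 in 21 of the 514 genes with at least 5 in each of the 10 others, where each of those 10, tested in the same way against the other 9, lacked at most 2. In frameshift ratio, 2 of the 2 other stiff tumours and 2 of the 2 other KO-host tumours lie within or above the range of the soft and of the WT-host tumours. As A9 and B5 stand out by being the only tumours low in this ratio, that outcome was fixed, and it does not test the group. A shared donor or strain background predicts the same missing calls and stays open, as the labels give neither donor nor instrument per tumour.

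A further hypothesis was calls concentrated in genomic segments that hold several genes. Of the top 50 with a known place, 20 lay within 5 genes of another of the 50 in the GRCm38.p6 gene order, against a median of 0 and at most 10 in 10000 random sets (permutation p = 0.0001, the smallest they can give). Arhgap30, Nit1, Pfdn2, Klhdc9 and Nectin4 form one such run, and Plekhf1, Ccne1 and Gm5591 another. The second run was nearly absent from A9 and B5, with 4 and 6 protein-altering variants in Plekhf1 against 33 to 53 in the other tumours, 1 and 0 in Ccne1, and 0 and 0 in Gm5591. Segments where the Balb/c genome differs strongly from the reference are a possible explanation, though one common to all tumours does not account for those 2, and Tyr, altered in albino Balb/c mice, had a protein-altering variant in 1 of 12 tumours. Misplaced reads of copied segments are another; positions and allele fractions, which could separate them, are not in the tables used here.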
